A study of Homo sapiens with 6 samples.

How the data were processed

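Total RNA of 6 PANC-1 samples, 3 labelled siControl and 3 labelled for the siRNA against NR4A1, had been hybridised as biotin-labelled cRNA to Illumina BeadChips. The sample titles write the second group with the letters siTR4A1, while the series design names siNR4A1, and the name siNR4A1 is used here. BeadStudio is named in the submitters' processing notes, with no version; the chip type was not given in the sources used here. The deposited intensity table holds linear signals per probe, not normalized per the file headers and not background-subtracted, as no value lies at or under 0. It carries no detection p-values and no control probes. The deposited log2 table holds the authors' processed values. These equal quantile normalization of the log2 signals within 0.005, the rounding of the table, with no background step, and each of its columns has a median of 6.74.

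The intensities were the main source, and the authors' log2 values an alternative. The design fixed before the data were examined foresaw limma's neqc where detection p-values or controls exist and, where they do not, normexp background correction with an offset of 50, quantile normalization and log2; the latter was used, with an offset of 16 as the alternative. Its detection filter needed detection p-values as well and was replaced, before any fit, by a rule on the signals. The background of an array was the mode of its log2 signals (density bandwidth 0.03), its spread was taken from the values below the mode, and a probe was detected above the 95% point of that background. Probes detected on at least 3 arrays were kept. A log2 change after the offset understates the change of dim genes.

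Of all probes on the arrays, 27036 carried a current symbol, 4626 were renamed through a synonym of 1 gene, 132 through a synonym shared by several genes, and 3486 through an Entrez number, using the RefSeq gene table of GRCh38.p14 for names only. A further 8626 kept the name in the file, 3270 had none and 54 held a date in place of a symbol. Of 19066 probes kept, 18189 had a name and stood for 13715 genes, and 877 did not. For a gene with several probes the one with the highest mean stood for the gene; 3516 genes had more than 1 kept probe, and of 49 named genes with several, 45 had all probes on one side of 0. A probe of a gene not detected in any array of a group gives a bound. No coordinates are given, since the genome build was not given in the sources used here.

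Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3) on all 6 arrays with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p of a single gene comes from this limma fit unless another is named. Where single probes of a named gene are compared with the threshold, the same model was fitted to and adjusted over all 18189 kept probes with a name. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 35 lists tested. The genes named were NR4A1 to NR4A3 and the 12 genes tied to NR4A1 by the study's group, the 12 largest rises and 12 largest falls past the threshold with groups that did not overlap and the probe detected on all 3 arrays of the higher group, and up to 4 members per list past the threshold (2 for control lists, and the 2 with the smallest p where none passed); 140 genes fell under the rule, and the text prints those that carry each account. Provisional names were left out of the largest changes. A name counted as provisional where the file gave a LOC number, or another placeholder that is still the current symbol; genes whose placeholder has since been replaced, such as SKIDA1 and LAMTOR1, were kept. This reading and the resolving of shared synonyms were settled after the largest changes had been seen; this left out RPS28P6 at -1.79, LOC730288 at -1.63, RPS28P4 at -1.47 and C9orf40 at 1.30.

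The steps were tested on simulated signals built from each probe's mean, the array brightness and random noise, with about 98 genes changed by each of 2 known sizes. A first version took each probe's own spread as its true spread and recovered 7.14% of changes of 0.5 and 53.1% of changes of 1 on the log2 scale, over 13650 genes. That missed a recovery floor set beforehand without a basis, the floor was dropped, and its noise had 3.31 prior degrees of freedom against 13.2 in the real fit, because the sampling error of each spread was counted again. The second version, made after that result was seen, used limma's moderated spreads, with 12.0 prior degrees of freedom. It recovered 36.7% and 87.6%, over 13170 genes, with 7 false calls and 0 calls when no gene was changed. Its median SE was 0.095 against 0.117 in the real fit, so the second recovery is optimistic. In both versions the changed genes were drawn from those detected on all 6 arrays, so recovery of genes detected on fewer was not measured. The offset shrank a simulated change of 1 to a median of 0.72. Of 500 random lists on unchanged data, 2.4% had a camera p under 0.05, and a list of 30 genes shifted by 0.3 passed. The simulated noise was independent between genes, so the 2.4% does not cover lists of genes that vary together. The shifted list was required to pass and checks only that the steps run.

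The alternatives covered the background step, the offset, the scaling, the authors' values, the filter, the handling of probes, a replicate block, the variance model, array weights, a fold threshold, the list test and leaving out each array. Scaling on the median of detected probes and cyclic loess were added after the data had been seen. Both added scalings followed the result with array medians equalized. Gene length was first tested on protein-coding genes alone, against the written plan, and then on all tested genes with a length, which is the result given. Figures were drawn with matplotlib 3.10.9.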

Results

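Gene expression was measured on Illumina BeadChips in PANC-1 cells, an established human pancreatic cancer line, after transfection with a control small interfering RNA (siControl) or with one against the orphan nuclear receptor NR4A1 (siNR4A1). Each of the 2 groups held 3 arrays, and their number limits the precision. Between 18231 and 20407 probes were detected per array, and 13715 genes entered the comparison. Mean signal per array ran from 332 on siControl replicate 2 to 623 on siControl replicate 3, the brightest array. After normalization, Pearson's r across the tested genes lay between 0.990 and 0.993 within siControl, between 0.994 and 0.995 within siNR4A1 and between 0.978 and 0.988 across the groups. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

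The targeted gene was examined first. NR4A1 was below the detection threshold on all 6 arrays with each of its 3 probes, in control cells as well as after transfection with siNR4A1. The brightest of them, ILMN_2408566, had a signal of 98.8 ± 10.8 (SD, n = 3) in siControl and 106 ± 9.30 (SD, n = 3) in siNR4A1. Exact two-sided permutation tests of the 3 probes gave p = 1, p = 0.3 and p = 0.9, where 0.1 is the smallest p that 3 against 3 arrays can give. The arrays therefore hold no measurement of the knockdown at the mRNA level, and no direction is given for NR4A1. NR4A2, a second member of the family, differed by 0.21 ± 0.13 (SE) on the log2 scale with 1 detected probe, above the threshold on 1 siControl and 3 siNR4A1 arrays (limma, adjusted p = 0.270), and NR4A3 was not detected.

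**Figure D1:**
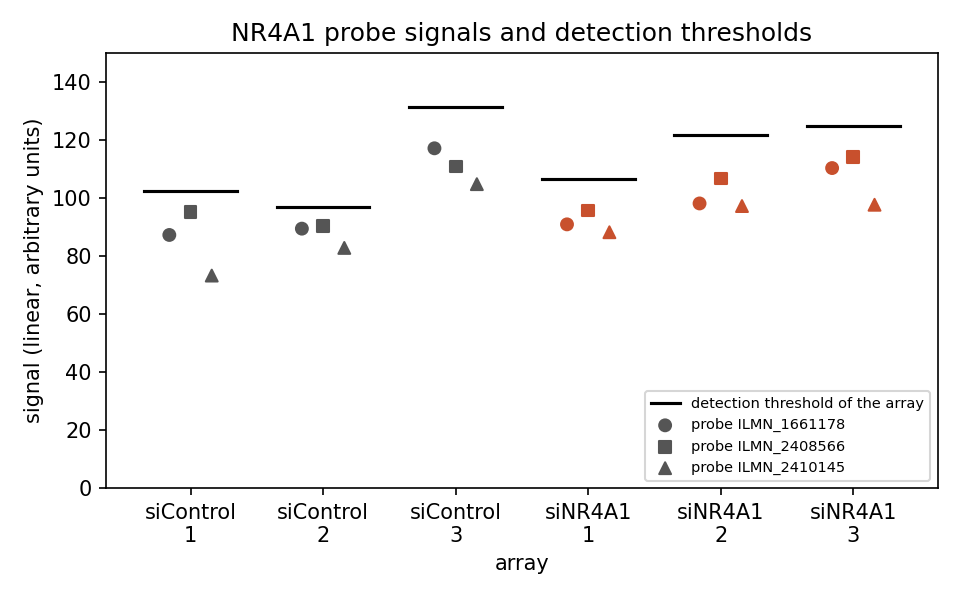
Signal of the 3 NR4A1 probes on each of the 6 arrays (points, linear scale) beside the detection threshold of that array (horizontal line). Every NR4A1 point lies under its line, from 73.3 to 117 in signal.

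The study's title places NR4A1 in oxidative and endoplasmic reticulum stress, and 12 genes that its group has linked to the receptor were followed whatever their test. IDH1, the cytosolic NADP-dependent isocitrate dehydrogenase, fell by 1.16 ± 0.11 (SE, n = 3 per group) on the log2 scale in siNR4A1, and both of its probes fell (adjusted p = 2.95e-06, limma). TXNDC5, a thioredoxin-domain protein of the endoplasmic reticulum, fell by 0.91 ± 0.11 (SE, n = 3 per group; limma, adjusted p = 4.02e-05), although 1 of its 3 probes, with a change of -0.54, missed the threshold at an adjusted p of 0.0829. DDIT3, which encodes the stress transcription factor CHOP, rose by 1.14 ± 0.13 (SE), and BIRC5, which encodes survivin and overlaps an antisense transcript, rose by 0.96 ± 0.12 (SE), with adjusted p-values of 1.83e-05 and 3.57e-05. The remaining 8 members did not pass: BCL2 differed by 0.37, CDKN1A by -0.28, MYC by -0.26, XBP1 by -0.14, SESN2 by -0.09, HSPA5 by -0.04 and ATF4 by 0.02, while EGFR differed by less than its SE of 0.11. BCL2 passed with array weights, at 0.41. Its probe was above the detection threshold on only 1 siControl and 2 siNR4A1 arrays, and that of SESN2 on 2 and 1. ATF4 had 3 probes, with changes from -0.35 to 0.02. Adjusted over the list alone, 3 members rose and 4 fell, and the list's camera adjusted p was 0.632. The list was chosen from the same group's work and is not independent evidence of its direction.

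**Figure D2:**
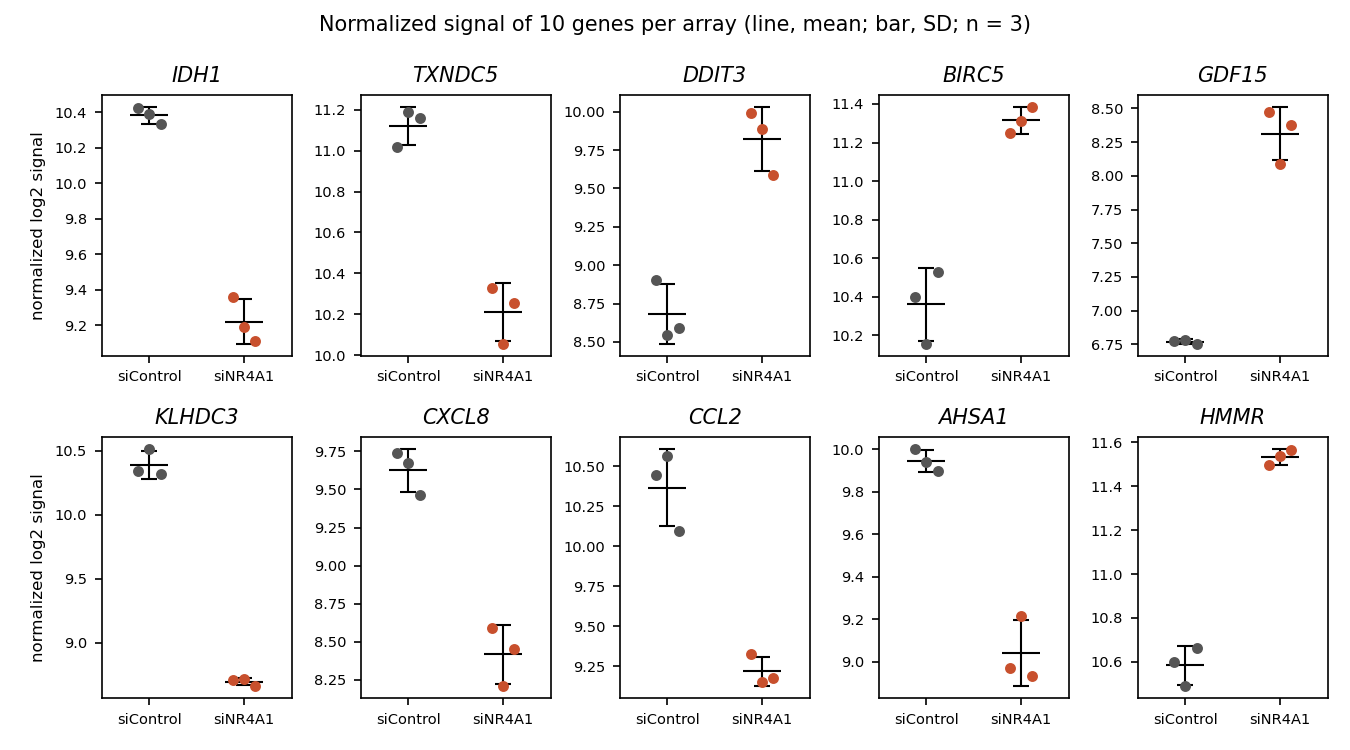
Normalized log2 signal of 10 genes on each array (points), with the group mean (line) and SD (bar, n = 3 per group). In every panel the 3 siNR4A1 arrays lie on one side of the 3 siControl arrays, as for IDH1, at 10.39 ± 0.05 (SD) in siControl and 9.22 ± 0.13 (SD) in siNR4A1.

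Across all genes tested, the largest rise among genes with a settled name was that of GDF15, a stress-responsive cytokine, at 1.54 ± 0.12 (SE) on the log2 scale or 2.91-fold. SKIDA1 rose by 1.30, CAMSAP2, a microtubule minus-end protein, by 1.29, SPOPL by 1.28, RBM24, an RNA-binding protein, by 1.26, and the imprinted noncoding RNA H19 and the membrane-curving protein BIN1 by 1.24 each. CRACR2B, HPCAL1 and the actin crosslinker FLNC rose by 1.16, 1.13 and 1.13, and SLC6A10P, whose sequence is close to that of SLC6A8, by 1.10. The largest fall among genes with a settled name, each read by its brightest probe, was that of KLHDC3, which fell by 1.70 ± 0.11 (SE) or 3.24-fold. A second, dimmer probe of ADIPOR1 went further, at -1.87. Other large falls were those of RAP1BL, a near-identical copy of RAP1B, at -1.57, LAMTOR1, a lysosomal scaffold for mTOR signalling, at -1.56, URM1 at -1.55, the adiponectin receptor ADIPOR1 at -1.51, ARL6IP6 at -1.50, and the gamma-secretase subunit APH1A at -1.47. NXT2 fell by 1.43, the p38 kinase activator MAP2K3 by 1.41, PIGF by 1.40 and RPS28, which has processed copies in the genome, by 1.39. These genes, like DDIT3, had adjusted p-values under the threshold and groups that did not overlap.

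In all, 2674 of 13715 genes changed, 1481 rising and 1193 falling (limma, Benjamini-Hochberg adjusted p under 0.05), or 19.5% of those tested. A change of at least 1.5-fold was met by 330 genes that rose and 361 that fell. The 3 arrays of one group lay on one side of the other 3 for 35.4% of genes, where chance gives 10%. With array medians equalized in place of quantile normalization, 0 genes passed in limma, against 1089 at an unadjusted p under 0.05, every named gene's call was lost, and the median change of all genes moved to 0.13; all 2674 genes kept their sign. Without siNR4A1 replicate 2 the count was 1773, with 939 rising and 834 falling, and without siNR4A1 replicate 3 it was 1507, with 768 rising and 739 falling. With medians of detected probes equalized 1254 genes changed, and among genes named here the calls of SOD2, MSMO1, SMAD6, EGR1, RPL15, CD14, HBA1, ALB and TBP were lost. With the mean of a gene's probes MAP2K3 stood at -0.85, RFC3 at -0.71, LSS at -0.38 and ABCC3 at 0.37, all past the threshold.

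Of 36 gene lists fixed in advance, 35 had enough tested members, and 5 passed limma's camera test at an adjusted p under 0.05. None of the 5 passed with an estimated correlation in place of the preset 0.01, where the lowest adjusted p was 0.308. The estimate lay under the preset for NF-kB (-0.048), NADPH supply (-0.044) and heat shock genes (0.0081). It lay above the preset for G2/M (0.071) and cholesterol synthesis (0.029). For lists under the preset, a higher correlation cannot account for the lost call. With an estimated correlation, limma also bases the test on the 4 residual degrees of freedom of the fit. With the preset it uses a number near the count of genes. At this number of arrays the estimated setting is thus far stricter whatever the correlation. Its lost calls therefore cannot tell whether correlation between genes gave the 5 calls. In the first test 7 lists had an unadjusted p under 0.05, and 5 in the second. The test fry, which asks whether a set's genes move one way on balance, passed 9. Median, mean and test differed in sign for 8 of the lists that did not pass, namely thiol enzymes, glutathione, endoplasmic reticulum chaperones, G1/S, mTOR, RNA interference, endothelial and other markers, and housekeeping controls.

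Genes of G2/M and mitosis were higher in siNR4A1: of 40 tested members, 17 rose, 0 fell and 23 did not pass, with a median log2 change of 0.31. Beside BIRC5, the hyaluronan receptor HMMR rose by 0.95 ± 0.11 (SE), the kinetochore motor CENPE by 0.71 ± 0.14 (SE) and the mitotic kinase PLK1 by 0.61 ± 0.11 (SE). The camera adjusted p was 5.69e-05, and the adjusted p was 0.310 with an estimated correlation. Adjusted over the list alone, 21 rose and 1 fell. The genes of G1/S and DNA replication went both ways, with 4 of 39 rising, among them cyclin D1 (CCND1) by 0.93 ± 0.13 (SE), and 8 falling, among them the clamp loader subunit RFC3 by 1.15 ± 0.14 (SE) and cyclin E2 (CCNE2) by 0.55 ± 0.11 (SE). That list's camera adjusted p was 0.607, and adjusted over the list alone 6 rose and 11 fell. Of 11 tested replication-dependent histone genes, 1 rose and 0 fell (camera, adjusted p = 0.497), as when adjusted over the list alone.

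NF-kB and cytokine genes were lower in siNR4A1. Of 16 tested members, 9 fell, 0 rose and 7 did not pass, with a median log2 change of -0.36. The chemokines CXCL8 and CCL2 fell by 1.21 ± 0.12 (SE) and 1.15 ± 0.13 (SE), and the NF-kB subunit RELB fell by 0.52 ± 0.12 (SE). CCL20 was detected on the 3 siControl arrays and on none of the siNR4A1 arrays, where only a bound can be given, and was at least 1.73-fold lower, set against the lowest detected signal of each array. The camera adjusted p was 0.000617, and the adjusted p was 0.308 with an estimated correlation. Adjusted over the list alone, 0 rose and 10 fell. Interferon-stimulated genes had 1 riser and 5 that fell among 26, including IFIT1 by 0.64 ± 0.12 (SE), and a camera adjusted p of 0.497; adjusted over the list alone, 5 rose and 6 fell.

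Cholesterol synthesis genes were lower as well: of 23 tested members, 8 fell and 2 rose, with a median log2 change of -0.26. Lanosterol synthase LSS fell by 0.67 ± 0.11 (SE), the sterol oxidase MSMO1 by 0.57 ± 0.13 (SE) and isopentenyl diphosphate isomerase IDI1 by 0.53 ± 0.11 (SE), while 1 of 3 LSS probes differed by 0.03. One of the 2 that rose was INSIG1, which restrains the sterol pathway's transcription factor, by 0.85 ± 0.12 (SE). The camera adjusted p was 0.000818, and the adjusted p was 0.308 with an estimated correlation. Adjusted over the list alone, 2 rose and 10 fell. In fatty acid synthesis 3 of 18 genes rose and 5 fell (camera, adjusted p = 0.497), with the desaturase SCD falling by 0.83 ± 0.12 (SE), ACSL3 by 0.54 and GPAM rising by 0.57. Adjusted over that list alone, 5 rose and 7 fell.

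Heat shock genes showed 7 members that fell, 1 that rose and 11 that did not pass among 19, with a median log2 change of -0.23. AHSA1, an activator of the chaperone HSP90, fell by 0.91 ± 0.11 (SE), HSPA1A, nearly identical to HSPA1B, by 0.63 ± 0.11 (SE), and DNAJB1 by 0.56 ± 0.12 (SE). The member that rose was the small heat shock protein HSPB1, by 0.41 ± 0.12 (SE, adjusted p = 0.0223, limma), a call lost without siControl replicate 1 (0.36) or 2 (0.34) and without siNR4A1 replicate 2 (0.37) or 3 (0.43), and with an offset of 16 (0.41). The camera adjusted p was 0.00289, the adjusted p was 0.308 with an estimated correlation, 0.133 with array medians equalized and 0.0504 with medians of detected probes equalized, in a range of 0.000261 to 0.308 over all alternatives. Adjusted over the list alone, 2 rose and 8 fell.

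In the endoplasmic reticulum lists the members went both ways. Among 25 chaperones and folding enzymes, 5 rose, among them SDF2L1 by 0.56 ± 0.12 (SE) and DNAJB9 by 0.46 ± 0.11 (SE), and 2 fell, calreticulin (CALR) by 0.70 ± 0.11 (SE) and TXNDC5. Among 26 genes of protein degradation at the endoplasmic reticulum and XBP1 targets, 3 rose, WFS1 by 0.68, SYVN1 by 0.54 and EDEM3 by 0.48, and 4 fell. A second probe of SYVN1 differed by 0.07 and one of EDEM3 by 0.05, and with the mean of a gene's probes SYVN1 stood at 0.31 and EDEM3 at 0.26, neither past the threshold. Neither list passed, at camera adjusted p-values of 0.904 and 0.638. The PERK-ATF4-CHOP arm and amino acid response had 9 of 40 genes rising, with GDF15, DDIT3 and the transcription factor CEBPB, by 1.10 ± 0.14 (SE), at the top, and 3 falling, among them the isoleucyl-tRNA synthetase IARS1 by 0.96 ± 0.12 (SE). Its median log2 change was 0.15, and it did not pass at an adjusted p of 0.123, although it did in 4 of 21 alternatives: array medians equalized (0.0170), medians of detected probes equalized (0.00875), no detection filter (0.0177) and fry (0.00943). The adjusted p ranged from 0.00875 to 0.564. Adjusted over each list alone, 5 chaperones rose and 2 fell, 3 degradation genes rose and 4 fell, and 9 genes of the PERK-ATF4-CHOP list rose and 4 fell.

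Of 13 tested genes of NADPH supply, 5 fell, 0 rose and 8 did not pass; whatever their test, 8 were lower and 5 higher in siNR4A1. Beside IDH1, the pentose phosphate enzymes PGLS and PGD fell by 0.66 ± 0.14 (SE) and 0.57 ± 0.12 (SE), and malic enzyme ME1 fell by 0.48 ± 0.11 (SE). The list's camera adjusted p was 0.0434, its median log2 change -0.10, and the adjusted p was 0.310 with an estimated correlation. The call was lost in 8 of 21 alternatives: the estimated correlation, ranks (adjusted p = 0.176), array medians equalized (0.204), medians of detected probes equalized (0.244), an offset of 16 (0.0688), the strict detection filter (0.0805), and leaving out siControl replicate 3 (0.107) or siNR4A1 replicate 1 (0.0563). The adjusted p ranged from 0.00359 to 0.310. Among 28 thiol and peroxide detoxification enzymes, 2 rose and 5 fell, including glutaredoxin GLRX by 0.82 ± 0.11 (SE) and manganese superoxide dismutase SOD2 by 0.47 ± 0.11 (SE), with a camera adjusted p of 0.497. The thiol list passed only with fry, toward lower values (adjusted p = 0.00971). Its median was 0.02 and its mean -0.07, so the sign of its center depended on the measure. Of 23 NRF2 targets 2 rose, among them the transporter ABCC3 by 0.62, and 4 fell, and of 18 genes of glutathione synthesis and transfer 0 rose and 1 fell, GSTK1 by 0.60; both lists had a camera adjusted p of 0.833. Adjusted over each list alone, 0 NADPH genes rose and 6 fell, 2 thiol enzymes rose and 6 fell, 3 NRF2 targets rose and 4 fell, and 0 glutathione genes rose and 1 fell.

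Autophagy and lysosome genes moved in both directions, with 5 of 30 rising and 6 falling (camera, adjusted p = 0.521). The 4 members with the largest changes all fell: ATG12, by 1.13 ± 0.11 (SE), the initiator BECN1, by 0.99 ± 0.13 (SE), and MAP1LC3B and GABARAPL1, which coat autophagosomes, by 0.97 ± 0.12 (SE) and 0.56 ± 0.12 (SE). Of 27 components and regulators of the mTOR pathway 4 rose and 3 fell, with LAMTOR1 and the cap-binding protein EIF4E, by 0.68, falling and PRKAG2 rising by 0.60 (camera, adjusted p = 0.833). Of 12 antiapoptotic genes 2 rose, BIRC5 and XIAP, by 0.71 ± 0.11 (SE), and 3 fell, with BCL2L1 falling by 0.70 ± 0.11 (SE) (camera, adjusted p = 0.914). Of 22 proapoptotic genes 1 rose, FADD by 0.45, and 2 fell (camera, adjusted p = 0.521). Of 25 p53 targets 4 rose and 3 fell (camera, adjusted p = 0.773). GDF15, also counted in the PERK-ATF4-CHOP list, rose by 1.54 and GADD45A by 0.57, while TIGAR fell by 0.55 and PLK2 by 0.54. Adjusted over each list alone, 7 autophagy genes rose and 8 fell, 7 mTOR genes rose and 6 fell, 4 antiapoptotic genes rose and 4 fell, 1 proapoptotic gene rose and 2 fell, and 5 p53 targets rose and 3 fell.

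In energy metabolism, glycolysis had 2 of 22 genes rising and 2 falling, with the mutase PGAM1 falling by 1.08 ± 0.13 (SE) on both probes (camera, adjusted p = 0.844). Oxidative phosphorylation had 3 of 44 genes rising and 4 falling, with NDUFA2 falling by 0.95 and UQCRC2 by 0.62 (camera, adjusted p = 0.632). Among 16 hypoxia targets 2 rose and 3 fell, and the adenylate kinase AK4 fell by 1.29 ± 0.15 (SE) on all 3 probes (camera, adjusted p = 0.497). Of 45 cytosolic ribosomal protein genes 1 rose, RPL22 by 0.51, and 3 fell, with RPL15 at -0.50 (camera, adjusted p = 0.484). The proteasome list had 6 of 31 genes falling, led by PSMB2 at -0.88 ± 0.11 (SE), and 1 rising, at a camera adjusted p of 0.0899. That list passed with no detection filter (adjusted p = 0.0177) and with the mean of a gene's probes (0.0259), in a range up to 0.851. Adjusted over each list alone, 2 glycolysis genes rose and 2 fell, 3 of oxidative phosphorylation rose and 4 fell, 2 hypoxia targets rose and 5 fell, 1 ribosomal gene rose and 2 fell, and 1 proteasome gene rose and 6 fell.

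Among 10 tested epithelial genes 0 rose and 0 fell, with CLDN1 at 0.27 and MUC1 at -0.21 (camera, adjusted p = 0.632). Mesenchymal genes had 2 of 18 rising, among them S100A4 by 0.51 ± 0.12 (SE), and 2 falling, led by the matricellular protein CCN2 by 0.75 ± 0.11 (SE) (camera, adjusted p = 0.914). Of 19 TGF-beta and YAP targets 6 rose, including SMAD6 by 0.52, and 3 fell (camera, adjusted p = 0.458). Among 22 immediate early genes and MAPK feedback regulators 4 rose, led by SPRED1 at 0.76, DUSP5 at 0.63 and EGR1 at 0.55, and 2 fell (camera, adjusted p = 0.497). That list passed only with fry, toward higher values (adjusted p = 0.0269). Of 17 receptor tyrosine kinases and ligands 1 rose and 1 fell, NRG1 by 0.57 (camera, adjusted p = 0.833). RNA interference genes had 4 of 13 rising, with DICER1 at 0.74 ± 0.13 (SE), and 3 falling, AGO3 among them when each gene is counted by its brightest probe (camera, adjusted p = 0.914). AGO3 went by -0.43 on its brighter probe and by 0.72 on the other, both past the threshold, and no direction is given for it; without siControl replicate 1 the gene's value was 0.55, and without siNR4A1 replicate 1 it was -0.38 and did not pass. Adjusted over each list alone, the counts stayed the same for epithelial, mesenchymal and TGF-beta genes, while 6 immediate early genes rose and 2 fell, 0 receptor kinases and ligands rose and 1 fell, and 5 RNA interference genes rose and 3 fell, AGO3 again counted by its brighter probe.

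Markers of other cell types were mostly not detected. Of 17 leukocyte markers 4 were tested, and CD68, which cultured tumour cells can also express, rose by 0.58 ± 0.11 (SE), as did CD14 by 0.44, a call lost without siNR4A1 replicate 3 (0.40). The camera adjusted p of these 4 genes was 0.357, and they passed only with fry, toward higher values (adjusted p = 0.000798). Of 18 further markers, of endothelial, erythroid, acinar and islet cells and with them the liver product albumin (ALB), 3 were tested, with HBA1 at 0.40 and ALB at -0.32, both past the threshold with all arrays. HBA1 lost its call without siControl replicate 2 (0.30) or 3 (0.41) and without siNR4A1 replicate 2 (0.30) or 3 (0.39), and ALB without any of 5 arrays, siControl replicate 3 excepted (-0.29 to -0.33). Both calls were also lost without background correction, with the authors' values and with no detection filter, HBA1's with an offset of 16 and ALB's with the robust variance; that list's camera adjusted p was 0.999. Of 13 housekeeping controls 2 rose and 1 fell, with TBP at -0.45, whose call was lost without siNR4A1 replicate 3 (-0.42); the camera adjusted p was 0.949. Adjusted over each list alone, 2 leukocyte markers rose and 0 fell, 1 endothelial or other marker rose and 1 fell, and 3 housekeeping controls rose and 1 fell.

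**Figure D3:**
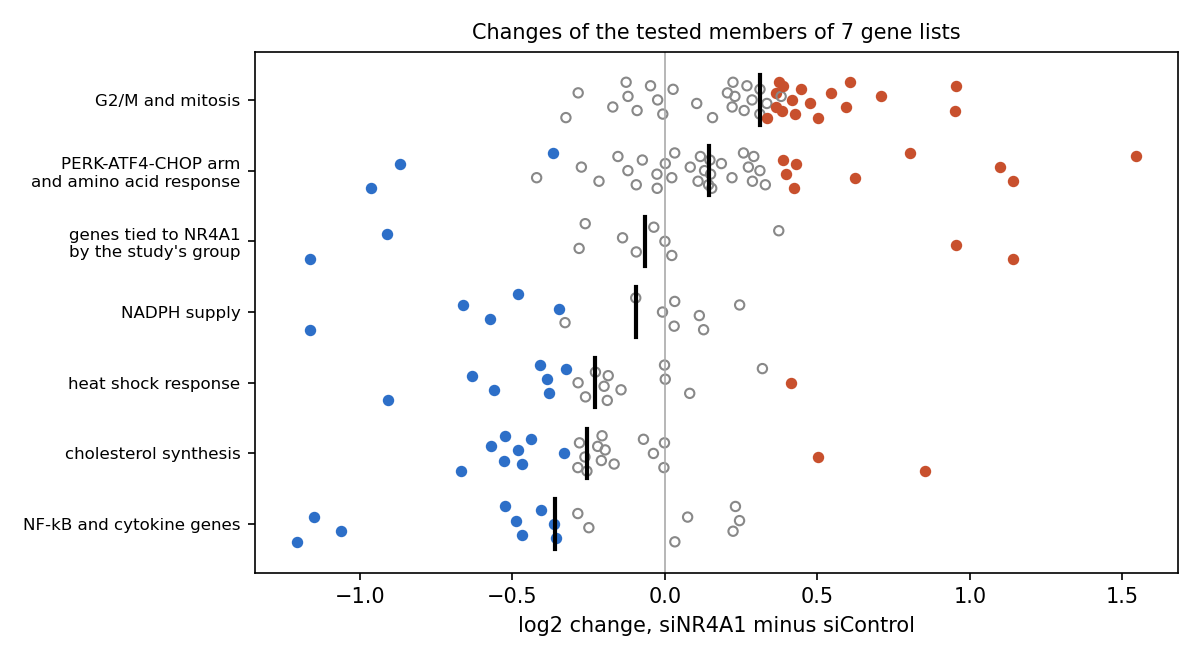
Log2 change, siNR4A1 minus siControl, of each tested member of 7 gene lists (points; filled red, rose; filled blue, fell; open, did not pass), with the list median (vertical bar) and spread vertically only for legibility. The medians run from -0.36 for NF-kB and cytokine genes to 0.31 for G2/M and mitosis.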

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

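No test in this part was chosen after its result was seen. Probes without a usable gene symbol took no part in the comparison of genes. Of 877 such probes kept, 24 were higher in siNR4A1 than in siControl and 9 were lower (limma, adjusted over these probes), with changes from -1.11 to 1.19 on the log2 scale; 28 of the 877 held a date in place of a symbol. Dates of this form arise when a spreadsheet converts gene symbols, and they were not converted back.

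The 2674 changed genes form the main pattern. Among the 10 splits of the 6 arrays into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0 genes; 10 splits are too few for a share under 0.05. For the lists, 1 split gave as many as the real 5, and the highest of the others gave 2, with the same limit. SiControl replicate 3 was the brightest array. Without it the median ratio of a changed gene's log2 change to the full one was 1.044, with quartiles of 0.96 and 1.13. That ratio covers only genes already called with the array, and leaving out any other array gave 0.96 to 1.015. It therefore cannot tell whether that array was the source. Without the array 3011 genes changed in limma, and 2375 of the 2674 still passed in the same direction. The count thus did not depend on that array. A difference between the transfections other than NR4A1 itself stays open and was not tested, since the knockdown could not be seen on these arrays and each group is 1 siRNA treatment.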

How the results depend on the processing

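Scaling on the median of detected probes and cyclic loess were chosen after seeing the data. Background correction, offset, filter, probe handling, authors' values, variance model, array weights and loess left the counts of changed, rising and falling genes within 1.5 times of 2674, 1481 and 1193. With array medians equalized, 0 genes changed, 0 rose and 0 fell, and all 2674 kept their sign with a median ratio of 1.08. The median over all probes lies in the background, so that shift leaves differences in array brightness in place. With medians of detected probes equalized, 1254 changed, 692 rose and 562 fell. A 1.5-fold minimum left 691, 330 and 361, and limma's treat against 1.2-fold left 412, 191 and 221, by construction. Leaving out 1 array gave 1507 to 3011 changed, 768 to 1714 rising and 739 to 1297 falling, on fewer arrays. Of lists, 0 passed with an estimated correlation, which also tests on 4 degrees of freedom, and 9 with fry, which asks another question. AGO3 reversed to 0.14 with the mean of its probes and ran from -0.48 to 0.55 on leaving out 1 array, with its other probe standing for it without siControl replicate 1. NR4A1 passed nowhere. Of 129 named genes past the threshold, 87 lost no call in the alternatives besides median scaling that tested them, which were 17 for most and 13 for CCL20, and 32 lost one on leaving out an array. With the replicate number as a block, 2998 genes changed. Deviations of same-numbered arrays correlated at 0.03, 0.08 and 0.17, against -0.13 to 0.06 for different numbers. Of the arrays, 5 of 6 matched best with their own number, so whether the numbers pair the arrays weakly stays open. A slide block was not run, as no slide is given. Signal over background limits dim genes such as NR4A1.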

Other observations

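The gene groups in this part and the tests on RPS28 and on the direction of large changes were chosen after the data were seen, unlike the test of gene length. In the tricarboxylic acid cycle, 3 of 22 genes fell, among them SUCLA2 at -0.48 and citrate synthase CS at -0.34, and 1 rose, SUCLG2 at 0.40. Among 20 cytosolic aminoacyl-tRNA synthetases 4 fell, led by IARS1 at -0.96 and CARS1 at -0.87, and 1 rose, FARSA at 0.50. In the Notch pathway the ligand JAG2 rose by 1.01 ± 0.12 (SE) and the target HES1 by 0.65 ± 0.15 (SE), while APH1A fell, and 17 of 20 did not pass. Of 28 genes of mRNA decay 3 rose, with the decapping enzyme DCP2 at 1.10 ± 0.12 (SE), and 3 fell, with the deadenylase CNOT6 at -1.16 ± 0.13 (SE). Of 17 nuclear receptors 2 rose, NR3C1 at 0.41 and RXRA at 0.34, and 0 fell. None of these 5 lists passed camera, with adjusted p-values from 0.241 to 0.977, and their genes were not rerun under the alternatives unless named elsewhere.

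RPS28 fell by 1.39 ± 0.11 (SE), and probes named for its processed copies RPS28P4, RPS28P6 and RPS28P7 fell by 1.47, 1.79 and 1.30. The other cytosolic ribosomal protein genes argue against a fall shared by the class, with a median of -0.0462, a median absolute deviation of 0.09 and a lowest member at -0.50. Whether the 4 detected probes named for RPS28 or a copy, all of which fell, read one RNA through shared sequence stays open, since probe sequences were not compared. Which locus the RNA came from, and whether the siRNA acts on it directly, was not tested.

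Among genes that moved at least 2-fold, 65 fell and 26 rose, a ratio of 2.50. With array medians equalized 36 fell and 86 rose, but that scaling moved the median change of all genes to 0.13. Counted relative to the median change of all genes, the ratio was 3.29, with 4.11 under cyclic loess, 2.28 to 4.06 on leaving out single arrays, and 1.35 with either set of medians equalized. Both of these scalings shift whole arrays, so the relative count is the same for both by construction. The relative count was taken up after the raw one had turned around. Whether the excess of falls holds under such scaling, and how much of it the scaling gives, thus stays open. Unintended targets of the siRNA stay open, since its sequence was not given in the sources used here.

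Spearman's rho of a gene's log2 change with its length in the genome was 0.0217 across 12202 tested genes, with a bootstrap interval of 0.0041 to 0.0395. Genes are not independent replicates, and other splits of the arrays reached a size of 0.115.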
